A study of Mus musculus with 2 samples.

How the data were processed

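Expression was measured on 2 Applied Biosystems mouse arrays, 1 for embryoid bodies labelled Elongin A+/+ and 1 for those labelled Elongin A-/-, both at day 4 after 2 µM retinoic acid. Per the labels, 1 µg of RNA was labelled with digoxigenin by in vitro transcription and detected with a chemiluminescent kit. The deposited values are intensities on a linear scale, since they are never negative, reach 4352 and have medians of 1.02 and 1.03. A median near 1 on both arrays points to scaling by the authors to the array median, but the normalization, background correction and any filter are not given in the sources used here. No scanner values or detection calls were used here. Arrays were assigned to genotype by their titles.

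Probes were named from the platform annotation, in which 14253 probes have 1 gene symbol, 243 have several and 17944 have none. Only probes with 1 symbol were named, giving 13697 genes, 527 of them with more than 1 probe. Of the probes with 1 symbol, 14245 had a gene identifier found in the RefSeq table of assembly GRCm38.p6, and 0 symbols needed updating. That table was used for chromosome names and gene order only, since the deposited values name no genome build, and no coordinates are given. A gene with several probes was represented by the probe with the highest mean log2 value.

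The rule for scaling was fixed before the data were examined: values as deposited unless any of 5 percentiles differed by 0.1 or more on the log2 scale. The 10th percentiles differed by -0.16, the 25th by -0.12 and the 75th by 0.15, so the arrays were quantile normalised. Log2 values of the arrays correlated at 0.932 over all probes and 0.962 over probes above the floor on both, across genes that are not independent replicates. The floor was the array median, 1.03 after normalisation. A gene was measured if it lay above the floor on at least 1 array, which held for 9568 genes (7529 on both, 1031 only on the array labelled Elongin A-/- and 1008 only on the array labelled Elongin A+/+), and 4129 genes lay below it on both. Values under the floor were set to the floor before the difference was taken, so a difference with 1 array at the floor is a bound. Intensities of genes are given after normalisation, and the array medians and highest values as deposited. Quantile normalisation forces the same distribution on both arrays, so a shift of most genes in 1 direction would not be seen.

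Genes were counted at a fixed size of 2-fold, with no p-value, because 1 array per genotype leaves no error to test against. For 24 gene lists, also fixed before the data were examined, the median log2 difference of measured members was set against 10000 random lists of the same size matched on mean level in 10 bins. The percentile describes these arrays only. Of the 707 genes in the lists, 14 are in more than 1 list and 451 were measured. Intervals of medians are binomial 95% intervals over members, given from 6 members on, and cover the spread between genes, not between cultures. The lists cover the elongin complex, transcription elongation, retinoic acid response, Hox, neural progenitor, neuronal, glial, neural crest, pluripotency, mesoderm, endoderm, cardiac and smooth muscle, blood and endothelium, epithelium and trophoblast, fibroblast and mesenchyme, proliferation, p53 and arrest, stress, hypoxia and glycolysis, signalling, imprinted, Y-linked and Xist, the Eloa neighbourhood and reference genes.

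Named genes followed a rule fixed in advance, among measured genes whose symbol is not a predicted or clone name: the 10 largest differences per direction above the floor on both arrays, the 5 largest bounds per direction, the elongin genes, up to 4 members per list with the largest absolute difference, and Pou5f1, Nanog, Tubb3, Map2, Nes, Pax6, Cyp26a1 and Rarb whatever their value. A further gene of this rule is not reported here. Examples in the report come from these, and genes chosen after their values were seen are said to be so. Probes of a gene disagreed with an SD of 0.43 above the floor on both arrays and 0.49 over all 302 measured genes with several probes. This is a technical and annotation error.

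Chosen in advance, 9 other settings of scaling, floor and probes were the values as deposited, centring on the median above the floor, a loess trend removed (span 0.3), floors at the 25th and 75th percentiles, no floor, a pseudocount at the floor, the mean over probes and genes with 1 probe only. Counts were also taken at 1.5-fold and 3-fold. Removing each chromosome's median and leaving out chromosomes 6, 8 and 11 were added after the data were seen. The analysis was tested on simulated data for Elongin A-/- against Elongin A+/+ with 9492 genes. Of 50 genes made 2-fold higher 88% were recovered with at least 50% of the log2 change, of 50 made 2-fold lower 86%, and of 50 made 4-fold different in each direction 100%. These changed genes were drawn only from bright genes with 1 probe and a mean log2 level above 3.06. Recovery of single dimmer genes was therefore not tested. A shift of 0.5 over 488 genes was recovered as 0.42, a shift of 0.8 in a list of 25 as 0.60, and 7 of 100 unchanged lists lay outside the middle 95%. The unchanged lists were random draws of genes with independent noise, so lists whose genes vary together were not tested. The software was Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.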

Results

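The data are gene expression arrays of mouse embryoid bodies, the 3-dimensional aggregates in which embryonic stem (ES) cells differentiate. The bodies were grown from ES cells that were either Elongin A+/+ or Elongin A-/- and were collected at day 4 after treatment with 2 µM retinoic acid, a signal that drives ES cells towards neural fates. Elongin A is the largest subunit of Elongin, a complex that stimulates elongation by RNA polymerase II. The comparison asks which genes differ in level between the genotypes after this treatment. There was 1 array per genotype, with 32440 probes each. Median intensities were 1.02 on the array labelled Elongin A+/+ and 1.03 on the array labelled Elongin A-/-, and the brightest probes reached 4352 and 3475. With 1 array each there is no replicate check and no error between cultures, so no difference given here was tested, and the number of arrays limits the precision. The only error the arrays hold is the disagreement between probes of the same gene, which had an SD of 0.43 (95% interval 0.38 to 0.48, 224 genes) on the log2 scale. Genotype, ES cell line, culture and array cannot be told apart in this design. Log2 differences below are the array labelled Elongin A-/- minus the array labelled Elongin A+/+, and a gene under the floor of 1.03 on 1 array has only a bound, written as "at least".

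Elongin A itself, the gene Eloa (also Tceb3, probe 572511), gave an intensity of 3.87 on the array labelled Elongin A+/+ and 3.57 on the array labelled Elongin A-/-, a log2 difference of -0.12. That is smaller than the disagreement between probes, and its sign turned with the values as deposited (0.05). The position of the probe relative to the deleted part of the gene is not given in the sources used here, so the probe checks nothing about the labels, and each direction below rests on the labels alone. The Elongin partners were also close: Eloc, the Elongin C gene, had 19.7 and 19.6, Elob, the Elongin B gene, 273 and 302, and Cul5, the cullin of the Elongin ubiquitin ligase, 26.2 and 22.2. The median of these 4 genes was -0.06, and 0.09 with the values as deposited. Among 25 measured genes of transcription elongation, 2 were at least 2-fold lower and none higher, with a median of -0.12 (95% interval over members -0.46 to 0.01) at percentile 16.7 of matched random lists, and -0.25 without genes on chromosomes 6, 8 and 11. The lower ones were Mllt3 (28.9 to 12.6) and Mllt1 (74.9 to 34.8), 2 subunits of the super elongation complex. Larp7, which binds the 7SK RNA, went from 169 to 88.7, and Ell, an elongation factor, from 12.9 to 22.6. Genes of chromosome 4 listed in advance as neighbours of Eloa were lower in 7 of 8 measured cases, all within 2-fold, with a median of -0.43 at percentile 0.46. Only their chromosome was taken from GRCm38.p6, and their distance to Eloa was not checked. Over all measured genes of chromosome 4 the median was -0.08, and 43.4% were higher. Luzp1 (-0.61) and Pnrc2 (-0.51) differed most.

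Cldn5 and Kdr, endothelial genes, were among the genes furthest higher on the array labelled Elongin A-/-, and Hoxc9, Hoxb9 and Hoxa7 among those furthest lower. Of 9568 measured genes, 647 were at least 2-fold higher, and 571 were at least 2-fold lower, with bounds counted at their bound. Of the 7529 above the floor on both arrays, 6784 (90.1%) lay within 2-fold. Higher genes made up 53.1% of those at least 2-fold apart, and 64.1% (800 against 449) with the values as deposited. The widest margins higher among genes above the floor on both arrays belonged to Dst, a cytoskeletal linker (1.14 to 44.8, 39.2-fold), Cldn5, a tight junction protein of endothelium (1.56 to 60.2, 38.5-fold), and Kdr, the VEGF receptor of endothelial and blood progenitors (2.23 to 54.4, 24.4-fold). The other probe of Dst was below the floor on both arrays, and values near the floor, such as those of Dst, Ctla2a, Clec1b, Sox7, Hoxb9, Hmbox1 and Fgf15 on their dimmer array, make these folds and their order approximate. Mepe (21.6-fold), Ctla2a (20.1-fold), Col26a1 (18.1-fold), Tmem119 (14.2-fold), Clec1b (13.4-fold), Sox7 (11.9-fold) and Adgra2 (10.4-fold) followed. Hoxc9 was lower by the widest margin (87.0 to 1.99, 43.6-fold), followed by Hoxb9 (13.7-fold), Hmbox1 (9.41-fold), Rbmx (8.33-fold), Hoxa7 (8.28-fold), Pik3ca (7.41-fold), Wnt4 (7.23-fold), Sp5 (7.19-fold), Olig3 (7.14-fold) and Fgf15 (7.12-fold).

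Among genes above the floor on 1 array only, the widest bounds higher were those of Olfr1180 (at least 39.3-fold), Ago4 (32.9-fold), Mrgprh (28.9-fold), Vmn1r64 (23.1-fold) and H1f8 (16.6-fold), of which Olfr1180, Mrgprh and Vmn1r64 encode sensory-type receptors. The widest bounds lower were those of Pck1 (at least 36.2-fold), Hoxc8 (26.7-fold), Tubb4a (26.7-fold), Myo3a (25.5-fold) and Grap2 (14.5-fold). Single probes carry most of these values. In 25 genes with another probe above the floor on both arrays and 1 probe at least 2-fold apart, the other probe was at least 1.5-fold apart in the same direction in 7 and had the same sign in 17.

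Blood and endothelial genes were higher as a group on the array labelled Elongin A-/-. Of 16 measured members 10 were at least 2-fold higher and none lower, and the median difference was 2.12 (95% interval over members 0.59 to 2.83), at percentile 100 of matched random lists. Besides Cldn5, the list included Tal1, a transcription factor of blood and endothelial progenitors (at least 10.6-fold higher), Hbb-bh1, an embryonic beta-globin (at least 8.07-fold), and Esam, an endothelial adhesion molecule (at least 7.10-fold). The bounds number 12 of the 16 members, among them Klf1 (-0.57) and Spi1 (-0.77), the 2 members lower on the array labelled Elongin A-/-. The other members named on the array, Cdh5, Tie1, Gata1, Alas2 and Ptprc, were below the floor on both arrays. Klf1, Spi1 and the members below the floor were looked at after their values were seen. With the floor at the 75th percentile 9 members were left, 3 of them at least 2-fold higher, with a median of 0.67.

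Mesoderm genes were higher too, with 6 of 13 at least 2-fold higher and none lower, a median of 0.93 (0.14 to 1.71) and percentile 99.98. Kdr led them, followed by Osr1 (1.16 to 4.44), Foxc2 (13.1 to 43.0) and Tcf21 (1.94 to 6.31), transcription factors of intermediate, paraxial and splanchnic mesoderm. These 13 were the measured part of 24 mesoderm genes named on the array. Eomes, Mesp1, Mesp2, Tbx6 and Msgn1, looked at after the values were seen, were below the floor on both arrays. Endoderm genes had a median of 0.73 (-0.04 to 0.90) at percentile 100, with 6 of 26 at least 2-fold higher and 2 lower. That median was 0.33 without genes on chromosomes 6, 8 and 11 and 0.44 with each chromosome's median removed. Sox7, an endoderm and endothelial transcription factor, led with 1.25 to 14.9. Fga, a fibrinogen chain, was at least 6.53-fold higher, but the other chains, Fgb and Fgg, were below the floor on both arrays. By any margin 18 of the 26 were higher and 8 lower. The regulators Foxa1 (4.59 to 2.58) and Foxa2 (2.65 to 1.56) were lower, while Gata6 (2.65 to 4.40) and Sox17 (5.71 to 10.6) were higher. Gata4 and Foxa3 were below the floor on both arrays. Fgb, Fgg and these regulators were looked at after the values were seen. Plat, the tissue plasminogen activator, went from 9.81 to 36.2 and lies on chromosome 8, while Afp, the alpha-fetoprotein gene of visceral endoderm, was at least 3.89-fold lower.

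Mesenchymal and epithelial lists were higher by less. Fibroblast and mesenchyme genes had a median of 0.39 (-0.18 to 0.99) at percentile 99.9, with 5 of 21 at least 2-fold higher and 1 lower. The collagen gene Col3a1 went from 41.8 to 152 and Col1a1 was at least 4.43-fold higher, while Col1a2 (-0.18) and Col5a2 (-0.40), looked at after the values were seen, were not higher. The connective tissue growth factor Ccn2 went from 16.5 to 3.38. Epithelial and trophoblast genes had a median of 0.42 (-0.74 to 1.16) at percentile 98.2, with 5 of 16 higher and 1 lower, and 0.27 with each chromosome's median removed. A median of 0.27 lies inside the random range found at the main setting (-0.36 to 0.40). Krt19, a keratin, was 4.43-fold higher, Perp was at least 2.53-fold higher and Cdx2, a caudal and trophoblast regulator, at least 2.84-fold lower. Cardiac and smooth muscle genes ran the other way, with a median of -0.60 (-1.68 to 0.73) at percentile 0.50, 4 of 13 lower and 1 higher. Their median was -0.31 with the floor at the 75th percentile. Tagln (41.4 to 8.29), Acta1 (6.27 to 1.32) and Actc1 (3.31 to 1.03), genes of the contractile apparatus, were lower, and the cardiac regulator Nkx2-5 was higher (3.66 to 8.01).

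**Figure D1:**
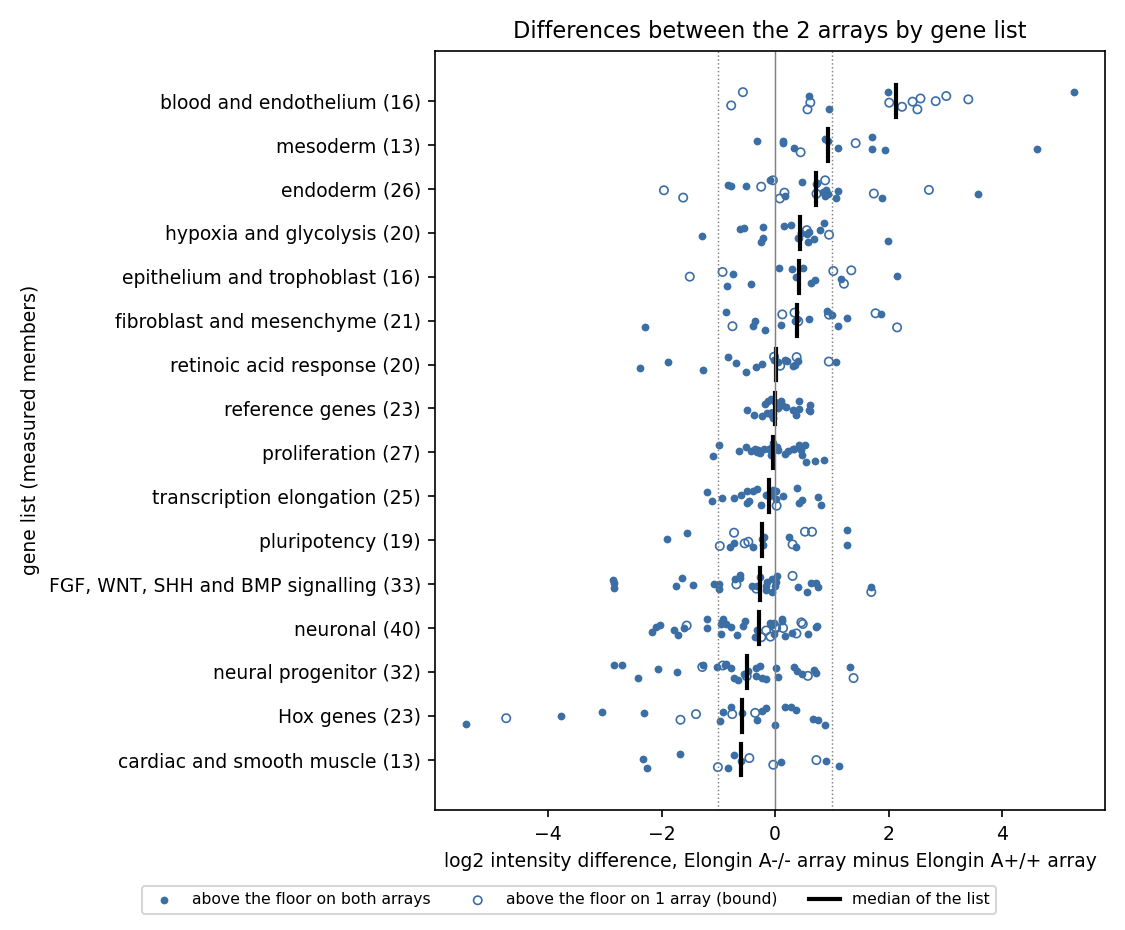
Log2 intensity difference (array labelled Elongin A-/- minus array labelled Elongin A+/+) of each measured member of 16 gene lists, with filled points for genes above the floor on both arrays, open points for bounds, a bar at each list's median and dotted lines at a 2-fold difference. Medians run from 2.12 for blood and endothelium to -0.60 for cardiac and smooth muscle genes.

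Hox genes, which set position along the body axis, were lower as a group on the array labelled Elongin A-/-. Of 23 measured Hox genes 7 were at least 2-fold lower and none higher, with a median of -0.58 (-1.39 to -0.00) at percentile 0 of matched random lists. The median was -0.92 without genes on chromosomes 6, 8 and 11, and -0.27 with the floor at the 75th percentile. Hoxc9 (87.0 to 1.99), Hoxc8 (27.4 to below the floor), Hoxb9 (16.2 to 1.18) and Hoxa7 (63.4 to 7.65) were lowest relative to the array labelled Elongin A+/+. Over paralogues 1 to 4 the median of 9 genes was -0.00 with 1 at least 2-fold lower, and over paralogues 5 to 10 the median of 14 genes was -0.84 with 6 lower, while all genes of paralogues 11 to 13 named on the array were below the floor on both arrays. That division was made after the values were seen, and the difference between its parts was not tested. Both parts held genes on either side, such as Hoxb4 (154 to 260) and Hoxd1 (11.8 to 2.38) in the first and Hoxb5 (32.7 to 51.8) and Hoxc5 (9.25 to 17.0) in the second, also chosen after their values were seen.

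**Figure D2:**
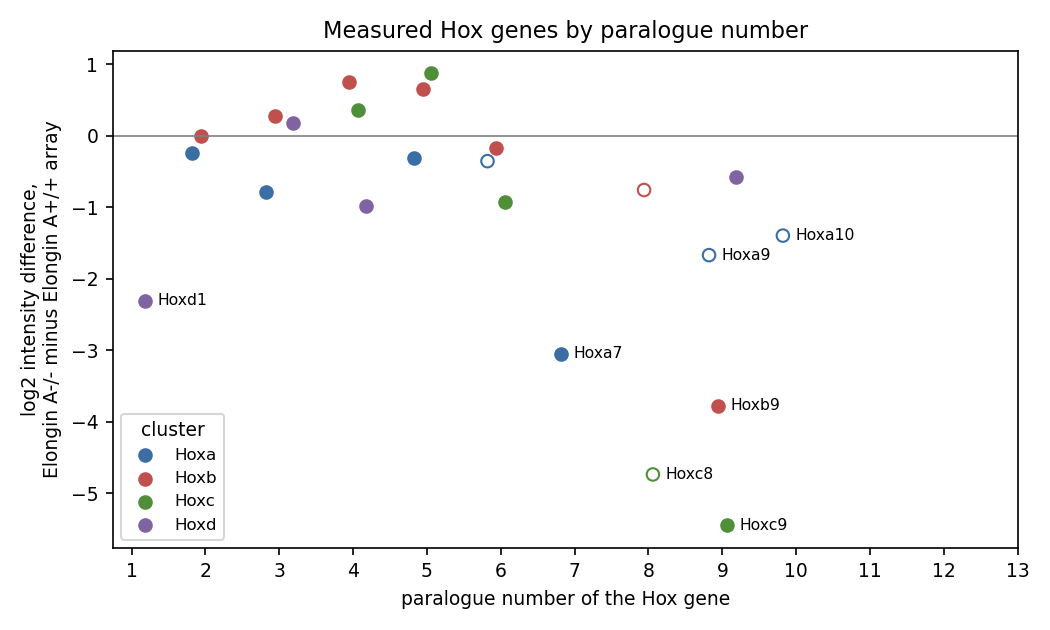
Log2 intensity difference (array labelled Elongin A-/- minus array labelled Elongin A+/+) of the 23 measured Hox genes against paralogue number, coloured by cluster, with open points for bounds and names at genes at least 2-fold apart. Hoxc9 lies lowest at -5.45, and genes of paralogues 1 to 4 have a median of -0.00.

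Neural progenitor genes were also lower on the array labelled Elongin A-/-, with 8 of 32 at least 2-fold lower and 2 higher, a median of -0.49 (-0.89 to 0.01) and percentile 0. The median was -0.26 with the floor at the 75th percentile. Olig3 (40.8 to 5.71) and Neurod4 (20.4 to 3.13), transcription factors of dorsal and differentiating progenitors, were lower, as were Zic2 (5.64 to 1.06) and Fabp7 (30.6 to 7.37). Pax6, another progenitor factor, had 9.32 and 12.9. Neuronal genes had a median of -0.28 (-0.87 to -0.02) at percentile 0.09, with 9 of 40 lower and none higher, and the median was -0.93 with the floor at the 75th percentile and -0.45 with no floor. Isl1 (4.47-fold), a motor and sensory neuron factor, Lhx5 (12.7 to 2.97), Nhlh2 (90.2 to 22.2) and Syt1 (5.22 to 1.51) were lower. With each chromosome's median removed, the neuronal median was -0.47. Tubb3, the neuronal beta-tubulin, differed little (179 and 168), but it lies on chromosome 8, whose measured genes had a median of 0.43. Map2 was below the floor on both arrays. Nes and Nanog were not named among the probes here.

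Signalling genes of the FGF, WNT, SHH and BMP pathways had a median of -0.27 (-0.68 to 0.00) at percentile 1.68, with 7 of 33 lower and 2 higher. Wnt4 (9.87 to 1.36), Sp5, a WNT target (14.7 to 2.04), Fgf15 (7.68 to 1.08) and Wnt3a (8.72 to 2.61) were lower. The median of this list was -0.16 with the values as deposited. Neural crest genes split, with 4 of 10 lower and 1 higher, a median of -0.24 (-1.99 to 0.64) and percentile 10.1, and that median was 0.04 with the floor at the 25th percentile and -1.03 at the 75th. Msx1 (23.9 to 5.75) and Msx2 (19.5 to 6.03) were lower, Dlx5 was at least 3.97-fold lower, and Sox9 was higher (2.03 to 6.01). Glial genes were higher in 5 of 5 measured cases, 2 of them by at least 2-fold, with a median of 0.76 at percentile 98.8. Of 10 glial genes named on the array only these 5 were measured, and 2 of the 5, Bcan and Cnp, were bounds. The median is the bound of Bcan, which had 1.74 on the array labelled Elongin A-/-. Slc1a3, an astroglial glutamate transporter, went from 2.36 to 6.06, and Aldoc, on chromosome 11, from 4.48 to 10.9.

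Genes of the retinoic acid response did not move as a group, while several of its targets differed by more than 2-fold. The median of 20 genes was 0.02 (-0.51 to 0.31) at percentile 63.0, the mean was -0.21, and the sign of the median turned with centring on the median above the floor (-0.06). Stra8, a retinoic acid target of germ cells, had 403 and 77.5, and Cyp26b1, which degrades retinoic acid, had 261 and 108. Both lie on chromosome 6. Cyp26a1, the related enzyme, had 159 and 89.8, Aldh1a1, which makes retinoic acid, had 6.30 and 1.70, and Rarb, a receptor gene induced by it, had 3.45 and 2.73. Crabp2, which carries retinoic acid to its receptors, was higher (324 to 678).

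Pluripotency genes had a median of -0.22 (-0.72 to 0.36) at percentile 14.2, with 2 of 19 higher and 2 lower, and -0.08 with the values as deposited. Klf5 (5.71 to 1.53) and Zfp42 (4.34 to 1.48) were lower, Dppa4 and Sall4 were higher (each 2.39-fold), and Pou5f1 was at least 1.65-fold lower from an intensity of 1.70. Proliferation genes had a median of -0.03 (-0.30 to 0.33) at percentile 43.7, which was 0.09 with the values as deposited, and 1 of 27, Cdk1 (2.30 to 1.08), was 2-fold lower. Genes of the p53 response, apoptosis and arrest had a median of -0.18 (-0.71 to 0.28) at percentile 10.6, with 1 of 21 higher and 2 lower, and -0.09 with the values as deposited. Cdkn2b, a cell cycle inhibitor, was 3.09-fold lower. Stress genes had a median of 0.12 (-0.25 to 0.51) at percentile 86.9 with 3 of 23 higher, and -0.25 without genes on chromosomes 6, 8 and 11. Fos (1.46 to 5.42), Ddit4 (11.1 to 31.2) and Ier3 (3.76 to 7.69) were the 3 higher genes. Hypoxia and glycolysis genes had a median of 0.44 (-0.21 to 0.60) at percentile 99.9, with 1 of 20 at least 2-fold higher, Adm (1.88 to 7.44), and 1 lower, Tpi1 (3.98 to 1.63).

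Imprinted genes had a median of -0.39 (-1.24 to 0.99) at percentile 0.25, with 2 of 14 higher and 4 lower. Igf2r went from 22.9 to 5.69 and Mest from 1081 to 453, while Sgce went from 33.5 to 73.9. The 4 measured genes of the list of Y-linked genes and Xist were Y-linked, 2 of them bounds, with a median of 0.42 at percentile 81.9. Uty was at least 1.86-fold and Uba1y at least 1.67-fold higher, Sry had 2.07 and 1.36, and Eif2s3y, the brightest, had 44.0 and 46.9. Reference genes had a median of 0.00 (-0.08 to 0.32) at percentile 57.9, with none of 23 at least 2-fold apart, and the median was -0.03 with centring on the median above the floor. Gapdh had 1836 and 2818, while the 2 probes of Rplp0 and of Eef1a1 disagreed in sign. Of 24 lists, 14 lay outside the middle 95% of random lists, 7 on each side, where chance alone gives about 1.2 if lists were independent and their genes unrelated. Genes of a list vary together, so these percentiles describe this pair of arrays only.

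Genes on chromosomes 8 and 11 were higher, and genes on chromosome 6 lower, across their whole length on the array labelled Elongin A-/-. The median difference was 0.43 (0.38 to 0.48) over 522 genes of chromosome 8, with 62 at least 2-fold higher and 12 lower. Chromosome 11 had 0.41 (0.36 to 0.46) over 803 genes, with 95 higher and 23 lower, and chromosome 6 had -0.26 (-0.31 to -0.22) over 518 genes, with 36 higher and 58 lower. The other 17 chromosomes with enough genes, X among them, lay between -0.13 and -0.00. Among genes above the 75th percentile on both arrays, 90.1% of those on chromosome 8 and 89.1% of those on chromosome 11 were higher. Chromosomes 8 and 11 held 157 of the genes at least 2-fold higher, 24.3% of them, against 13.8% of the measured genes. Without chromosomes 6, 8 and 11 there were 454 genes at least 2-fold higher and 478 lower, so that 48.7% were higher. Of the genes given by name above, Adgra2, Plat, Foxc2, Zfp42, Acta1, Tubb3, Ell, Cdh5 and Klf1 lie on chromosome 8 (GRCm38.p6). Hoxb4, Hoxb5, Hoxb9, Col1a1, Krt19, Sox9, Aldoc, Cnp and Wnt3a lie on chromosome 11. Hoxa7, Clec1b, Stra8, Cyp26b1, Mest, Sgce, Col1a2, Dlx5, Gapdh, H1f8 and Tpi1 lie on chromosome 6.

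**Figure D3:**
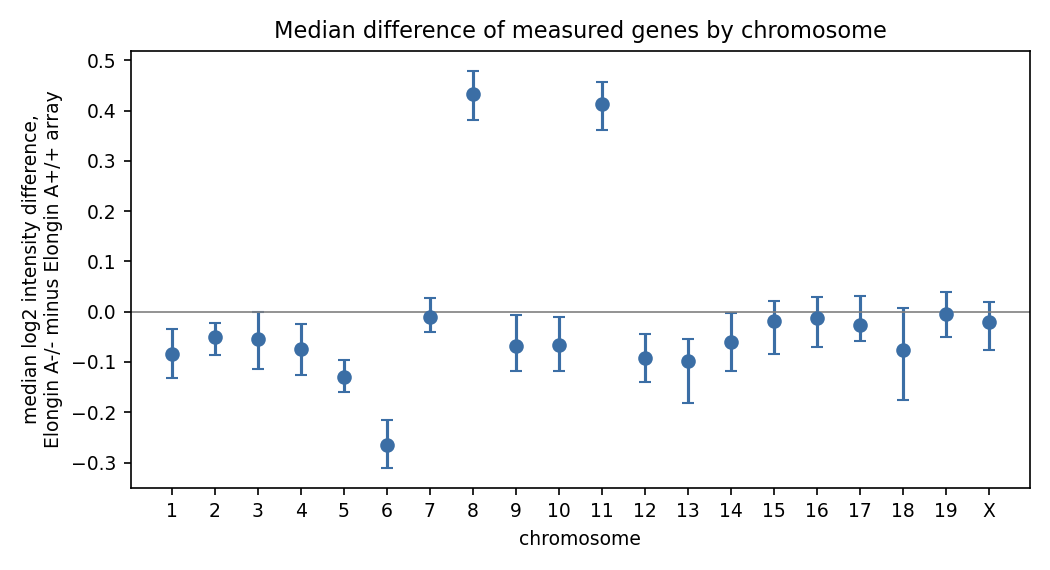
Median log2 intensity difference (array labelled Elongin A-/- minus array labelled Elongin A+/+) of measured genes per chromosome, with bars for the binomial 95% interval over genes. Chromosomes 8 (0.43) and 11 (0.41) lie above the others and chromosome 6 (-0.26) below them.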

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

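In this part the tests of fewer cells of the main type, of the array by which genes pass the higher floor and of the order of Hox paralogues were chosen after the results were seen, as were the patterns themselves. The comparisons above leave out probes with no gene name, and among these, 9 were at least 8-fold higher and 5 at least 8-fold lower on the array labelled Elongin A-/- while above the floor on both arrays. Probe 657627 went from 1.26 to 305 and probe 928328 from 545 to 3.39, wider margins than any named gene showed. These arrays hold no control for such signals, and what the probes measure is not given in the sources used here.

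Chromosomes 8 and 11 were higher and chromosome 6 lower on the array labelled Elongin A-/-. Intensity-dependent scaling is argued against, because the lower of the chromosome 8 and 11 medians was 0.43 with the loess trend removed, and so are a few neighbouring genes, because, with each chromosome divided into 10 equal segments in map order, 20 of 20 segments had medians above 0.2. A candidate explanation is an extra copy of both chromosomes in many of the cells labelled Elongin A-/-: the lower of the medians of their bright genes was 0.48, where 3 copies in place of 2 would give 0.58 if level followed copy number. For chromosome 6 the bright genes had a median of -0.32 (-0.36 to -0.29). That is just inside the range set for an extra copy in the cells labelled Elongin A+/+. In 8 of 10 segments the median lay under -0.2, as that rule asked. But the interval reaches outside the range, a requirement added after the value was seen, so this is left open. The rules for extra copies were set before the bright genes were looked at but after the chromosome shifts were seen. Bright genes are part of the same genes, so their medians are no independent check. Bright genes of the other 17 chromosomes had a median of -0.07, while the medians above are counted from 0. Counted from -0.07, the shifts of chromosomes 8 and 11 are larger. That of chromosome 6 is then smaller and falls short of the range. DNA was not measured, and whether the genotype or the history of the ES lines lies behind the shifts was not tested.

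For the blood and endothelial genes, higher on the array labelled Elongin A-/-, chromosome shifts are argued against by a median of 2.33 over the 12 members on other chromosomes, and noise of dim probes by a median of 0.67 with the floor at the 75th percentile, above 99.99% of random lists. Of the 9 members left there, 8 pass only on the array labelled Elongin A-/- and 0 only on the other, against 376 and 369 of all genes. Only 1 member is above that floor on both arrays. The median of 0.67 is therefore mostly of bounds, and it does not show a difference among members bright on both arrays. A smaller share of the main cell type, which would raise all other types alike, is left open: the gap to cardiac and smooth muscle genes was 2.73 (99% bootstrap interval over genes 0.64 to 4.01), which excludes it by the rule first set, but a higher floor, required only after that value was seen, gave 0.98 (-0.11 to 3.28) at the 75th percentile, and the gaps to endoderm, epithelium and fibroblast genes had intervals that include 0. Over 25 measured genes of a second endothelial list the median was 0.067, at percentile 71.3, which by the rule set in advance reads as not higher, but genes already seen to be far apart had been left out of the list, and for that reason it was judged undecided after the value was seen. More endothelial and blood progenitors in these bodies, through the genotype, the line or the culture, may still account for the fixed list, and the arrays cannot separate these. Some markers in that list, such as Cdh5, Tie1 and Gata1, were below the floor on both arrays, and Klf1 and Spi1 were lower.

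Hox and neural progenitor genes were lower on the array labelled Elongin A-/-. Chromosome shifts are argued against by a median of -0.54 over the 39 members on other chromosomes, and noise of dim probes by a median of -0.26 with the floor at the 75th percentile, at percentile 0.02. With that floor Hox genes alone lay at percentile 1.59, close to the random edge (-0.27 against -0.25), and neural progenitor genes at 0.45. Of the 37 members left, 11 pass only on the array labelled Elongin A+/+ and 1 only on the other. Over all genes these counts were 369 and 376. Fewer neural cells of every kind may or may not lie behind the lower Hox and neural progenitor genes: 11 bright neuronal genes had a median of -0.93, with an interval (-1.71 to 0.12) too wide to decide. Spearman's rho of paralogue number and difference was -0.52 across 23 Hox genes, which are not independent and of which 5 are bounds, but it restates the values that prompted it and so tests nothing further. A biological effect of the genotype on posterior identity was not tested, since genotype and line are the same split.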

How the results depend on the processing

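The settings that remove chromosome medians or leave out chromosomes 6, 8 and 11 were added after the data were seen. Apart from the Y-linked genes below, no result changed sign by more than its spread, and the report names the lists near 0 whose sign turned. Genes at least 2-fold higher and lower numbered 647 and 571; the counts were 1512 and 1416 at 1.5-fold, 213 and 178 at 3-fold, 1075 and 980 with the floor at the 25th percentile, 141 and 118 with it at the 75th and 1080 and 982 with no floor, as looser or stricter limits must give, and stayed within 1.5 times in the other 16 cases. Values as deposited gave -0.18, 0.53 and 0.51 for chromosomes 6, 8 and 11, which includes the shift of the median of all genes from -0.017 to 0.075. Chromosome 6 was -0.31 and chromosome 11 0.46 with the floor at the 75th percentile, and chromosome 8 was 0.48 with no floor. Of 264 list medians under alternatives 261 stayed within the main value's 95% interval over members (within the probe SD for lists of under 6); the others were neuronal genes at -0.93 with the floor at the 75th percentile, glial genes at 1.28 with no floor, where the cause was not tested for either, and Y-linked genes at -0.017 with chromosome medians removed, by construction. Those intervals cover the spread between genes and are wide, so staying within them is a loose limit for a change of processing. With the floor at the 75th percentile, blood and endothelial genes at 0.67 in place of 2.12 counted as staying. So did Hox genes at -0.27 in place of -0.58. The probe SD was 0.55 with the floor at the 25th percentile, 0.34 at the 75th and 0.35 with a pseudocount. Of 929 values of named genes at least 2-fold apart, 0 changed sign and 34 came under 2-fold; 150 of all 1255 values of named genes moved by more than the probe SD. Low signal over background limits single values: probes below the floor on both arrays differed by at least 2-fold in 21.2% of cases before the floor was applied, while by mean level the share was 37.3% and 31.6% in the first 2 groups of 10% around and above the floor and 2.74% in the brightest 10%. Leaving out a replicate is not possible with 1 array per genotype. No paired analysis was possible because each genotype has 1 array.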

Other observations

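In this part the endothelial genes, and the subsets and extension of the second endothelial list, were chosen after the results were seen. Several endothelial and blood-progenitor genes outside the fixed lists were higher on the array labelled Elongin A-/-, and they were picked because they were. Etv2, the transcription factor that starts the endothelial and blood lineage, went from 3.09 to 19.3 (6.25-fold), Fgd5 from 1.89 to 9.52 and Mmrn2 from 2.92 to 10.4. Ramp2, a subunit of the adrenomedullin receptor whose gene lies on chromosome 11, was at least 16.3-fold higher, while its partner Calcrl was below the floor on both arrays and the related Ramp3 went from 12.8 to 6.81. Cd34 was at least 7.11-fold and Lyve1 at least 5.67-fold higher.

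The second endothelial list left out genes already seen to be far apart, so its outcome leans towards no difference. It had 50 genes. Of these, 36 were named on the array and 25 were measured. The other named genes, among them Erg, Robo4 and Flt4, were below the floor on both arrays. Of the 25 measured genes, 4 were at least 2-fold higher and 3 lower, with a median of 0.067, inside the random range of -0.30 to 0.28. Sparcl1 went from 11.5 to 36.4, while Cd93 was at least 2.33-fold and Vwf at least 1.98-fold lower. Over the 18 genes off chromosomes 6, 8 and 11 the median was 0.32, at percentile 98.9, and over 7 genes with the floor at the 75th percentile it was 0.34, at percentile 97.2. With the 12 genes picked for being higher added, the median of 37 genes was 0.65, which leans the other way. Neither value decides whether endothelial genes outside the fixed list are higher.

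Probes with no gene name resembled the named genes in number: of 9050 measured, 615 were at least 2-fold higher and 614 lower, together 13.6%. With each chromosome's median removed, rho of Hox paralogue number and difference was -0.54. Hox cluster c, on a chromosome with a median of -0.02, held the 2 Hox genes with the most negative differences, Hoxc9 and Hoxc8.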
